A study of Mus musculus with 96 samples.

How the data were processed

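ATAC-seq was done on nuclei tagged in hepatocytes (HEP-INTACT mice) or in macrophages (MAC-INTACT mice) and captured on beads. Per the labels, libraries were sequenced in pairs of reads, and macrophage samples were run as technical duplicates. The series states that fasting began at ZT12 and that fed controls were taken at the same times. The samples at 3, 8, 16 and 24 h thus fall at ZT15, ZT20, ZT4 and ZT12. There are 16 groups of 4 female mice, and the mouse is the unit of replication.

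The authors deposited 1 table per cell type with a signal value per peak and mouse, named normalized counts, beside the gene of the nearest TSS. Per the labels they used BWA 0.7.5a-r405, SAMtools, HOMER and DESeq2 with the mm10 genome, without stating the role of each tool or its settings. Each peak is 200 bp wide. All deposited values of a column are whole multiples of 1 step, within a tolerance of 0.01 of a read, so that they are reads divided by 1 factor per library. How the factor was set is not stated. The macrophage table holds 1 column per mouse, so the authors had joined the technical runs, and how they did so is not stated. The authors also deposited log2 fold changes of fasted over fed mice at each time. Their adjusted p values are deposited beside these, with no statement of the adjustment, and were used only for the comparison of calls.

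Tests used limma 3.58.1 in R 4.3.3 on log2 of the deposited value plus 2, with 8 group means per cell type and a trend in the prior variance. Peaks with a mean of at least 10 normalized reads were tested, which left out 5 hepatocyte peaks and 0 macrophage peaks. Fasted and fed mice were compared at each time, with Benjamini-Hochberg adjustment over the tested peaks of that comparison and a threshold of 0.05. Moderated F tests asked whether the fasting effect differed between times and whether time changed a peak in fed mice. The comparisons, tests, gene lists and most alternatives were fixed before the data were examined.

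There were 17 fixed gene lists: gluconeogenesis, fatty acid oxidation and ketogenesis, glucocorticoid response, insulin signalling and FOXO targets, fatty acid and triglyceride synthesis, cholesterol synthesis, circadian clock, amino acid catabolism and urea cycle, autophagy and lysosome, growth hormone and STAT5 axis, acute phase, bile acid and xenobiotic metabolism, NF-kB inflammatory response, interferon response, immediate early and AP-1, macrophage lipid handling, and antigen presentation. A further 7 lists held markers of hepatocytes, Kupffer cells and macrophages, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, monocytes and neutrophils, and lymphocytes. A list took the peaks whose nearest TSS is that of a list gene within 50 kb. It was tested against the other peaks with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists within a comparison.

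Peaks to name were set by a rule fixed beforehand. In each comparison these are the 6 opened and 6 closed peaks of largest log2 fold change among those that passed with no overlap between the 4 fasted and 4 fed mice, 1 peak per gene, and up to 3 passing peaks of smallest p from each fixed list. Predicted genes and hosts of small RNAs were passed over in the text, 7 of 237 named peaks in hepatocyte and 6 of 180 in macrophage nuclei. Some of these peaks are not reported here.

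Shared calls between times were compared with the product of the shares by a hypergeometric test. Overlap of the peaks of both cell types was taken with bedtools 2.31.1. Peaks within 1 kb of the TSS were called promoter peaks and compared by Fisher's exact test. All tests are two-sided but the hypergeometric ones.

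Alternatives were other offsets, filters, scalings (median centring, quantile normalization), variance models, a block on sets of library numbers, edgeR 4.0.16 with TMM and DESeq2 1.42.0 on the recovered reads, a minimum fold, promoter peaks only, an overlap of 0.5 of a peak, and each mouse left out in turn. Reads in peaks as a covariate, the leaving out of 2 macrophage libraries and the leaving out of the 16 h mice were chosen after seeing the data. The tests were tested on simulated data, reads drawn from a negative binomial at each peak's mean with changes of known fold. At most 0.0400% of unchanged peaks were called in a comparison. All simulated peaks of a cell type shared 1 dispersion (0.0108 in hepatocyte and 0.00346 in macrophage nuclei). No shift between libraries other than depth was simulated. This share is thus not an error rate for the data. Copies of a library under 2 names were checked for. The highest share of peaks with equal reads in a pair was 3.43% among hepatocyte and 3.70% among macrophage libraries. Sequence motifs and sequencing reads were not analysed here.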

Results

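Chromatin accessibility was measured by ATAC-seq in nuclei isolated from hepatocytes and from macrophages of mouse liver. Mice were fasted for 3, 8, 16 or 24 h from ZT12 or fed ad libitum and taken at the same times, with 4 female mice in each of the 16 groups. An opened peak has more reads in fasted than in fed mice and a closed peak has fewer, each at an adjusted p under 0.05 in limma. Levels are normalized reads, mean ± SD of 4 mice. Log2 fold changes are given ± SE and carry an offset of 2 normalized reads, so that they understate changes from a level near 0. A fold is 2 raised to that change or, for a fall, to its size. A peak is named by the gene whose annotated transcription start site (TSS) lies nearest in mm10, which does not show that the peak regulates that gene.

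Reads in the 46832 listed hepatocyte peaks numbered 4334668 ± 821505 per mouse (SD, n = 32), from 2458156 to 6098645. Those in the 30170 listed macrophage peaks numbered 3492422 ± 693581 (SD, n = 32), from 1729720 in fasted 16 h replicate 4 to 4637873. At this depth, 200 peaks were changed per simulated comparison, 50 for each fold. Changes of 2-fold were recovered in 92% to 100% of cases in hepatocyte nuclei and 98% to 100% in macrophage nuclei. Changes of 1.5-fold were recovered in 34% to 46% and 64% to 80%. More peaks passed in each comparison of the data, which loosens the adjusted threshold, so that these shares are not estimates for the data.

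After 3 h of fasting, hepatocyte nuclei opened peaks near Mt2, Pck1 and Cyp4a14 and closed peaks near Car3 and Angptl8. The promoter peak of Mt2, a metallothionein that binds zinc and copper (chromosome 8, 94172380 to 94172580), rose from 3.35 ± 2.06 in fed to 85.7 ± 17.5 in fasted mice, a log2 fold change of 4.10 ± 0.40 (adjusted p = 3.92e-09). A peak 7357 bp downstream of the TSS of Pck1, the cytosolic enzyme that commits oxaloacetate to glucose synthesis (chromosome 2, 173160330 to 173160530), rose 5.92-fold, from 29.2 ± 20.7 to 159 ± 12.2. A peak 11183 bp downstream of Cyp4a14, a fatty acid omega-hydroxylase (chromosome 4, 115484858 to 115485058), rose from 2.23 ± 1.13 to 55.3 ± 21.4, a log2 fold change of 3.73 ± 0.37. Near Igfbp1, a secreted binding protein of insulin-like growth factors, the level rose from 1.36 ± 0.943 to 52.7 ± 31.6. Near Tat, which starts tyrosine breakdown, it rose from 4.95 ± 2.29 to 60.3 ± 24.0. The closed peak with the largest change lay 9159 bp downstream of Car3, a carbonic anhydrase (chromosome 3, 14872597 to 14872797), with 64.0 ± 7.10 in fed and 0.645 ± 0.781 in fasted mice.

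Closed peaks at 3 h also included that of Angptl8, a secreted inhibitor of lipoprotein lipase (chromosome 9, 21838001 to 21838201), where the level dropped from 83.7 ± 14.4 to 2.88 ± 2.36 (log2 fold change -4.23 ± 0.43, adjusted p = 1.02e-08). The promoter peak of Scd1, the desaturase that makes oleate, was 5.99-fold lower in fasted mice, and a peak near Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 8.35-fold lower. Insig1, which retains the sterol sensor in the endoplasmic reticulum, fell 5.85-fold at a peak 8113 bp downstream, and Pltp, a phospholipid transfer protein, fell 4.83-fold. Opened peaks lay near Lpin1, a phosphatidate phosphatase (7.94-fold, promoter), Ddit4, an inhibitor of mTORC1 (12.4-fold), Pdk4, a kinase that inhibits pyruvate dehydrogenase (2.95-fold), Angptl4, an inhibitor of lipoprotein lipase (3.18-fold), and Ppargc1a, a transcriptional coactivator (2.55-fold). Zbtb16, a zinc finger repressor, rose 3.16-fold at its promoter, Gpt2, an alanine aminotransferase, 4.69-fold, and Slc7a2, an arginine transporter, 4.04-fold. Gabarapl1 and Ulk1, of the autophagy machinery, rose 1.91-fold and 1.64-fold. Among the peaks named for 3 h in both paragraphs, no fasted mouse overlapped a fed mouse.

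At 3 h, 10136 of 46827 tested hepatocyte peaks passed, 5292 opened and 4844 closed, of which 1253 and 1093 changed at least 2-fold. The glucocorticoid response list had 82 opened and 3 closed of 198 peaks (90 and 6 adjusted over the list alone; adjusted p = 2.28e-15, but adjusted p = 0.143 with an estimated correlation). Gluconeogenesis had 49 opened and 2 closed of 143 peaks (52 and 2 adjusted over the list alone; adjusted p = 7.37e-09, but adjusted p = 0.216 with an estimated correlation). Fatty acid oxidation and ketogenesis had 52 opened and 7 closed of 186 peaks (58 and 9 adjusted over the list alone; adjusted p = 7.37e-09, but adjusted p = 0.143 with an estimated correlation). Cholesterol synthesis moved the other way, with 8 opened and 37 closed of 116 peaks (9 and 46 adjusted over the list alone; adjusted p = 7.39e-07, and adjusted p = 0.0223 with an estimated correlation). Among them is a peak near Sc5d, a sterol desaturase (2.66-fold lower). Of the camera calls on the metabolic and immune lists, those that hold with an estimated correlation are cholesterol synthesis at 3, 8 and 16 h in hepatocyte nuclei, and in macrophage nuclei glucocorticoid response at 3, 8 and 24 h, cholesterol synthesis at 3 h and interferon response at 24 h.

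After 8 h, the largest rise in hepatocyte nuclei was that of the peak 11183 bp downstream of Cyp4a14, with 2.52 ± 1.72 in fed and 89.9 ± 26.7 in fasted mice (log2 fold change 4.38 ± 0.37, adjusted p = 4.83e-11). Lpin1 had a peak 9443 bp upstream (chromosome 12, 16620309 to 16620509) that rose from 9.85 ± 1.72 to 166 ± 20.6, and a peak 49768 bp upstream of Il1r1, the receptor of interleukin 1, rose 11.4-fold. Pdk4 rose 4.63-fold and Angptl4 4.43-fold. The largest fall lay 59694 bp upstream of Shcbp1, a signalling adaptor (chromosome 8, 4839161 to 4839361), from 142 ± 14.4 in fed to 6.20 ± 1.87 in fasted mice (log2 fold change -4.16 ± 0.31, adjusted p = 3.90e-12). Cish, a feedback inhibitor of STAT5 signalling, fell 5.04-fold, Sqle, an oxygenase of sterol synthesis, 5.05-fold, and Fads1, a fatty acid desaturase, 3.71-fold.

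Other opened peaks at 8 h lay near Nr1d1, the clock repressor REV-ERB alpha (2.69-fold), Ciart, another clock repressor (2.42-fold), Bnip3, a mitophagy receptor (3.29-fold), and the transcription factors Cebpd (5.75-fold) and Cebpb (2.39-fold). Further ones lay near G6pc, the glucose-6-phosphatase that releases glucose (2.29-fold), and Tdo2, which opens the tryptophan ring (2.73-fold). Closed peaks lay near Akt1, a kinase that carries insulin signals (2.51-fold), Cyp27a1, a sterol hydroxylase (3.89-fold), Prodh, which breaks down proline (2.32-fold), and Tap2, a peptide transporter (4.39-fold). In all, 15937 peaks passed at 8 h, 9512 opened and 6425 closed, or 59.7% opened. Median centring of the libraries gives 7061 opened and 7938 closed, or 47.1% opened. Fatty acid oxidation and ketogenesis had 100 opened and 14 closed of 186 peaks (107 and 14 adjusted over the list alone; adjusted p = 6.06e-09, but adjusted p = 0.125 with an estimated correlation). Cholesterol synthesis had 11 opened and 38 closed of 116 peaks (13 and 41 adjusted over the list alone; adjusted p = 2.71e-06, and adjusted p = 0.0272 with an estimated correlation). The growth hormone and STAT5 axis had 9 opened and 27 closed of 122 peaks (9 and 25 adjusted over the list alone; adjusted p = 0.00200, but adjusted p = 0.554 with an estimated correlation).

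After 16 h, the Cyp4a14 peak stood at 1.41 ± 1.92 in fed and 43.0 ± 18.0 in fasted hepatocyte nuclei, a log2 fold change of 3.77 ± 0.37 (adjusted p = 1.69e-09). Kif13a, a kinesin, rose 6.73-fold and Dgat2, which makes triglyceride from diglyceride, 4.51-fold. Fgf21, a hormone that liver secretes, rose 2.92-fold at its promoter (chromosome 7, 45615473 to 45615673), from 22.0 ± 6.50 to 65.9 ± 2.08. Peaks near Shcbp1 and near Stk38l, a kinase of the Hippo family, were 18.3-fold and 13.5-fold lower in fasted mice. The promoter peak of Srebf1, the transcription factor that drives fatty acid synthesis, was 4.04-fold lower, and that of Sqle 2.66-fold lower. Akt1 fell 4.26-fold.

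Opened peaks at 16 h also lay near Klf15, a transcription factor of amino acid breakdown (3.31-fold), Il1r2, a decoy receptor of interleukin 1 (5.17-fold), and the clock repressors Per2 (5.59-fold) and Cry2 (2.73-fold). Others lay near Apcs, a pentraxin (3.08-fold), Abca1, a cholesterol exporter (2.71-fold), and Nr1i3, a xenobiotic receptor (1.75-fold). Ppargc1a, opened upstream at 3 and 8 h, was 1.94-fold lower at a different peak, 1612 bp downstream of its TSS. Fbp1, fructose-1,6-bisphosphatase, was 1.88-fold lower, with overlap between fasted and fed mice. In all, 14896 peaks passed at 16 h, 8916 opened and 5980 closed, or 59.9% opened. The median log2 fold change of all peaks was 0.10, and after median centring of the libraries 5680 opened and 7359 closed, or 43.6% opened. Fatty acid oxidation and ketogenesis had 80 opened and 14 closed of 186 peaks (86 and 16 adjusted over the list alone, 64 and 17 after centring; adjusted p = 1.12e-05, but adjusted p = 0.407 with an estimated correlation). Fatty acid and triglyceride synthesis had 21 opened and 52 closed of 179 peaks (22 and 54 adjusted over the list alone, 15 and 60 after centring; adjusted p = 0.000175, but adjusted p = 0.643 with an estimated correlation). Cholesterol synthesis had 12 opened and 38 closed of 116 peaks (13 and 40 adjusted over the list alone, 11 and 44 after centring; adjusted p = 1.25e-05, and adjusted p = 0.0452 with an estimated correlation). Glucocorticoid response had 31 opened and 25 closed of 198 peaks (31 and 21 adjusted over the list alone, 27 and 33 after centring; adjusted p = 0.689), so that more of its peaks are opened than closed as deposited and fewer after centring.

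After 24 h, the promoter peak of Cdkn1a, an inhibitor of cell cycle kinases (chromosome 17, 29093600 to 29093800), rose from 17.4 ± 5.15 to 101 ± 14.7 in hepatocyte nuclei (log2 fold change 2.45 ± 0.28, adjusted p = 7.30e-08). The Cyp4a14 peak rose from 2.86 ± 1.21 to 56.1 ± 23.0, Nnmt, a methyltransferase of nicotinamide, 4.82-fold, Got1, an aspartate aminotransferase, 2.73-fold, and Ddit4 3.04-fold. Plin5, which coats lipid droplets, rose 2.10-fold at its promoter and Pdk4 1.71-fold at its promoter. Scd1 fell 8.85-fold at a peak 13618 bp downstream (chromosome 19, 44393991 to 44394191), from 61.0 ± 20.6 to 4.83 ± 0.735 (log2 fold change -3.15 ± 0.32, adjusted p = 7.80e-09). Shcbp1 fell 16.2-fold, Insig1 4.55-fold, Thrsp, a lipogenic nuclear protein, 4.72-fold, and Srebf1 4.20-fold at its promoter.

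Further opened peaks at 24 h lay near Fkbp5, a cochaperone of the glucocorticoid receptor (1.58-fold), Slc25a15, an ornithine carrier of the urea cycle (1.52-fold), and Oat, ornithine aminotransferase (2.27-fold). Opened peaks were also found near Alas1, which starts haem synthesis (1.95-fold), Hamp, the iron hormone hepcidin (1.47-fold), and Lamp1, a lysosomal membrane protein (1.64-fold). Closed peaks lay near Tlr2, a receptor of bacterial lipoproteins (2.68-fold), Nfkb2, an NF-kB subunit (2.52-fold), Pappa2, a protease of growth factor binding proteins (7.68-fold), Nr0b2, a bile acid responsive repressor (3.67-fold), and Becn1, an autophagy regulator (2.01-fold). In all, 17182 peaks passed at 24 h, 11867 opened and 5315 closed, or 69.1% opened. The median log2 fold change of all peaks was 0.16, and after median centring of the libraries 4683 opened and 6936 closed, or 40.3% opened. Of peaks changed at least 2-fold, 1958, 1283 and 491 were opened and 2013, 1883 and 1734 closed at 8, 16 and 24 h, so that closed peaks are the more numerous among these at each of those times. Amino acid catabolism and urea cycle had 95 opened and 6 closed of 196 peaks (103 and 6 adjusted over the list alone, 57 and 8 after centring; adjusted p = 3.42e-05, but adjusted p = 0.474 with an estimated correlation). Gluconeogenesis had 67 opened and 2 closed of 143 peaks (72 and 3 adjusted over the list alone, 46 and 4 after centring; adjusted p = 3.51e-05, but adjusted p = 0.474 with an estimated correlation). Glucocorticoid response had 90 opened and 6 closed of 198 peaks (95 and 6 adjusted over the list alone, 63 and 10 after centring; adjusted p = 3.42e-05, but adjusted p = 0.474 with an estimated correlation). Cholesterol synthesis had 22 opened and 27 closed of 116 peaks (24 and 27 adjusted over the list alone, 8 and 35 after centring; adjusted p = 0.00265, but adjusted p = 0.360 with an estimated correlation).

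The fixed lists not yet described for hepatocyte nuclei are given at the time of their lowest adjusted p. Insulin signalling and FOXO targets had 24 opened and 9 closed of 124 peaks at 3 h (29 and 13 adjusted over the list alone, 25 and 10 after centring; adjusted p = 0.00935 toward opening, but adjusted p = 0.258 with an estimated correlation). Its peak near Eif4ebp1, a repressor of translation, was 1.48-fold higher. Autophagy and lysosome had 24 opened and 6 closed of 109 peaks at 3 h (24 and 7 adjusted over the list alone, 24 and 7 after centring; adjusted p = 0.0236 toward opening, but adjusted p = 0.258 with an estimated correlation). Immediate early and AP-1 genes had 26 opened and 2 closed of 109 peaks at 3 h (26 and 2 adjusted over the list alone, 27 and 2 after centring; adjusted p = 0.000289 toward opening, but adjusted p = 0.258 with an estimated correlation). Peaks near Fos and Nr4a1 were 2.85-fold and 2.19-fold higher. Interferon response had 4 opened and 8 closed of 45 peaks at 3 h (4 and 8 adjusted over the list alone, 4 and 7 after centring; adjusted p = 0.00331 toward closing, but adjusted p = 0.143 with an estimated correlation). Irf1, an interferon regulatory factor, was 2.21-fold lower and Stat2, a signal transducer of interferon, 2.17-fold higher. Antigen presentation had 0 opened and 4 closed of 20 peaks at 3 h by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR (0 and 4 adjusted over the list alone; adjusted p = 0.0443 toward closing, but adjusted p = 0.143 with an estimated correlation). B2m was 1.76-fold lower and Ciita, the master regulator of MHC class II, 1.61-fold lower. The circadian clock list had 49 opened and 8 closed of 143 peaks at 24 h (49 and 9 adjusted over the list alone, 22 and 11 after centring; adjusted p = 0.0747). Acute phase had 15 opened and 7 closed of 78 peaks at 3 h (17 and 7 adjusted over the list alone; adjusted p = 0.136). Bile acid and xenobiotic metabolism had 20 opened and 16 closed of 123 peaks at 3 h (22 and 17 adjusted over the list alone, 20 and 15 after centring; adjusted p = 0.314). NF-kB inflammatory response had 9 opened and 14 closed of 74 peaks at 24 h (7 and 13 adjusted over the list alone, 2 and 15 after centring; adjusted p = 0.0764). Macrophage lipid handling had 28 opened and 11 closed of 87 peaks at 16 h (31 and 11 adjusted over the list alone, 18 and 12 after centring; adjusted p = 0.478). Of 68 tests of lists in hepatocyte nuclei, 26 passed with the preset correlation and 3 with the estimated one as well. The median, the mean and the test of a list differed in sign in 13 tests, of which 1 passed, fatty acid and triglyceride synthesis at 24 h (median log2 fold change 0.06, mean -0.08, lower than other peaks by the test).

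In macrophage nuclei, 3 h of fasting opened peaks near glucocorticoid response genes and closed few. The largest change lay 23146 bp upstream of Ddit4 (chromosome 10, 59974816 to 59975016), which rose from 5.16 ± 0.899 to 82.5 ± 26.2 (log2 fold change 3.52 ± 0.28, adjusted p = 2.08e-13). Tsc22d3, a leucine zipper protein that restrains inflammation, rose 3.04-fold, Klf9, a Kruppel-like factor (chromosome 19, 23134914 to 23135114), 2.05-fold, and Pik3r1, a regulatory subunit of PI3 kinase, 4.31-fold. Uvrag, an autophagy regulator, rose 2.89-fold. Birc3, an inhibitor of apoptosis, rose 2.52-fold, Nfkbia, the inhibitor of NF-kB, 1.48-fold, Fos, an AP-1 subunit, 2.26-fold, and Per1, a clock repressor, 1.35-fold. The peak with the largest fall lay near Gbp11, a guanylate-binding protein, 2.08-fold lower, followed by Tmem241, a membrane protein (1.81-fold), and Lta, the cytokine lymphotoxin alpha (1.81-fold). Aacs, which activates ketone bodies for lipid synthesis, was 1.38-fold lower, Scd1 1.31-fold lower and Srebf1 1.32-fold lower at its promoter.

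At 3 h, 548 of 30170 tested macrophage peaks passed, 506 opened and 42 closed, of which 170 and 1 changed at least 2-fold. Without fed 3 h replicate 1 the count is 345, and without fasted 3 h replicate 4 it is 319. Glucocorticoid response had 33 opened and 0 closed of 101 peaks (45 and 1 adjusted over the list alone; adjusted p = 1.94e-39, and adjusted p = 1.73e-05 with an estimated correlation) by limma, where closed peaks at an unadjusted p under 0.05 number 1 and edgeR calls 0. Cholesterol synthesis had 0 opened and 0 closed of 32 peaks (0 and 2 adjusted over the list alone; adjusted p = 1.51e-09, and adjusted p = 0.0459 with an estimated correlation) by limma, with 0 opened and 15 closed at an unadjusted p under 0.05, 0 and 0 by edgeR, and a median log2 fold change of -0.16.

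After 8 h, the same Ddit4 peak rose in macrophage nuclei from 5.23 ± 1.84 to 80.6 ± 19.2 (log2 fold change 3.52 ± 0.28, adjusted p = 6.08e-13). Armc12, an armadillo repeat protein, rose 6.09-fold, Mrap, an accessory protein of the ACTH receptor (chromosome 16, 90743579 to 90743779), 4.86-fold, Cxcr4, a chemokine receptor, 4.03-fold, and Tsc22d3 2.28-fold. Apoe, an apolipoprotein that macrophages secrete, rose 1.37-fold at its promoter and Plin2, a lipid droplet coat protein, 1.41-fold. Lpl, lipoprotein lipase, fell 2.14-fold at its promoter (chromosome 8, 68880465 to 68880665), from 39.0 ± 7.38 to 17.4 ± 5.32. Tyk2, a kinase of cytokine receptors, fell 2.32-fold and Gna15, a G protein subunit, 2.26-fold. Cd74 and H2-Aa, of MHC class II antigen presentation, fell 1.48-fold and 1.38-fold at their promoters, Cd40, a costimulatory receptor, 1.57-fold, and Ccl2, a chemokine that draws monocytes, 1.40-fold.

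At 8 h, 1990 macrophage peaks passed, 493 opened and 1497 closed, or 24.8% opened. Median centring gives 856 opened and 820 closed, or 51.1% opened. The count falls when single mice are left out, to 815 without fed 8 h replicate 1, 1044 without fed replicate 2, 1308 without fed replicate 3, 695 without fasted 8 h replicate 3 and 850 without fasted replicate 4. Glucocorticoid response had 30 opened and 0 closed of 101 peaks (35 and 2 adjusted over the list alone; adjusted p = 1.29e-29, and adjusted p = 0.000150 with an estimated correlation) by limma, where closed peaks at an unadjusted p under 0.05 number 4 and edgeR calls 0. Antigen presentation had 0 opened and 9 closed of 43 peaks (0 and 13 adjusted over the list alone, 0 and 6 after centring; adjusted p = 7.82e-05, but adjusted p = 0.213 with an estimated correlation) by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR. Interferon response had 1 opened and 4 closed of 55 peaks (1 and 15 adjusted over the list alone, 1 and 2 after centring; adjusted p = 0.000862, but adjusted p = 0.213 with an estimated correlation).

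After 16 h, closed macrophage peaks outnumbered opened ones as deposited. Thsd4, an extracellular matrix protein, fell 3.38-fold at a peak 45916 bp upstream (chromosome 9, 60187036 to 60187236; log2 fold change -1.76 ± 0.21, adjusted p = 1.76e-07), Creb1, the cyclic AMP response factor, 2.96-fold at a peak 47274 bp upstream, and Gbp3, another guanylate-binding protein, 2.18-fold. Arntl, the clock activator BMAL1, fell 2.08-fold at a peak 27012 bp upstream, Nr4a1, an orphan nuclear receptor, 1.99-fold, Insig1 1.90-fold, Akt2, an insulin signalling kinase, 1.80-fold, Cxcl1, a neutrophil chemokine, 1.78-fold, and Il1rn, the antagonist of interleukin 1, 1.63-fold. Opened peaks were fewer, with Pik3cb, a PI3 kinase subunit, 3.40-fold higher (18.8 ± 4.24 to 73.0 ± 32.2), and Agfg2, an ArfGAP family protein, 3.15-fold (log2 fold change 1.65 ± 0.15, adjusted p = 2.45e-10). Tfeb, the lysosome transcription factor, rose 1.90-fold, Plin2 1.83-fold and Abcg1, a cholesterol exporter, 1.42-fold. The Ddit4 peak that had risen at 3 and 8 h had a log2 fold change of 0.28 ± 0.28.

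At 16 h, 6415 macrophage peaks passed, 1144 opened and 5271 closed, or 17.8% opened. The median log2 fold change of all peaks was -0.10, and after median centring of the libraries 3063 opened and 3183 closed, or 49.0% opened. Without fasted 16 h replicate 1 the count is 3822. Without fasted replicates 1 and 4, left out after seeing the data, 329 opened and 1147 closed, with 2 fasted mice left. Fewer mice can call fewer peaks, so that this count is not ranked against those of 4 fasted mice at 8 and 24 h. Without those 2 libraries, 26 of the 57 macrophage peaks named by the rule for 16 h missed the threshold. Glucocorticoid response had 17 opened and 8 closed of 101 peaks (17 and 8 adjusted over the list alone, 26 and 2 after centring; adjusted p = 6.13e-05, but adjusted p = 0.191 with an estimated correlation). Interferon response had 1 opened and 18 closed of 55 peaks (2 and 20 adjusted over the list alone, 3 and 14 after centring; adjusted p = 0.0203, but adjusted p = 0.386 with an estimated correlation). Mx1, an antiviral GTPase, fell 1.59-fold and Usp18, an ISG15 protease, 1.36-fold at their promoters. Fatty acid oxidation and ketogenesis had 6 opened and 3 closed of 39 peaks (7 and 3 adjusted over the list alone, 12 and 2 after centring; adjusted p = 0.000731, but adjusted p = 0.172 with an estimated correlation).

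After 24 h, peaks near glucocorticoid response genes were open and peaks near antiviral genes closed in macrophage nuclei. Ddit4 rose 5.16-fold at a peak 13310 bp upstream (18.7 ± 12.5 to 83.3 ± 13.9), and Rgs2, an inhibitor of G protein signalling, 6.63-fold. Ston1, an endocytic adaptor (chromosome 17, 88581517 to 88581717), rose 7.96-fold (log2 fold change 2.99 ± 0.33, adjusted p = 2.50e-08), Cdkn1a 1.55-fold and Klf9 1.57-fold at its promoter. Oasl1, an antiviral protein, fell 2.61-fold at its promoter (chromosome 5, 114922916 to 114923116), from 46.4 ± 7.08 to 16.6 ± 3.54 (log2 fold change -1.38 ± 0.19, adjusted p = 1.08e-06). Mx1 fell 1.85-fold at its promoter and Ifih1, a sensor of viral RNA, 1.69-fold at its promoter. B2m, the light chain of MHC class I, fell 2.03-fold, Egr1, an immediate early factor, 2.37-fold, Tlr2 1.58-fold, Msr1, a scavenger receptor, 1.66-fold, Scd1 1.90-fold and Srebf1 1.55-fold. Map1lc3b, which coats autophagosomes, and Foxo3, a transcription factor that insulin restrains, rose 1.29-fold and 1.37-fold.

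At 24 h, 3402 macrophage peaks passed, 905 opened and 2497 closed, or 26.6% opened, against 45.9% after median centring (1688 and 1990). Without fed 24 h replicate 1 the count is 1824 and without fed 24 h replicate 2 it is 2231. Of peaks changed at least 2-fold, 79, 25 and 103 were opened and 21, 147 and 136 closed at 8, 16 and 24 h, so that opened peaks are the more numerous among these at 8 h. Glucocorticoid response had 35 opened and 1 closed of 101 peaks (41 and 2 adjusted over the list alone, 44 and 1 after centring; adjusted p = 2.81e-20, and adjusted p = 0.00180 with an estimated correlation). Interferon response had 0 opened and 29 closed of 55 peaks (1 and 35 adjusted over the list alone, 0 and 28 after centring; adjusted p = 7.95e-14, and adjusted p = 0.00491 with an estimated correlation) by limma, with 1 opened at an unadjusted p under 0.05 and 0 by edgeR. Antigen presentation had 0 opened and 7 closed of 43 peaks (0 and 8 adjusted over the list alone; adjusted p = 0.00101, but adjusted p = 0.378 with an estimated correlation) by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR.

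The fixed lists not yet described for macrophage nuclei are given at the time of their lowest adjusted p. Fatty acid and triglyceride synthesis had 0 opened and 3 closed of 31 peaks at 3 h by limma, with 1 opened at an unadjusted p under 0.05 and 0 by edgeR (0 and 5 adjusted over the list alone; adjusted p = 0.00192 toward closing, but adjusted p = 0.0698 with an estimated correlation). Insulin signalling and FOXO targets had 2 opened and 1 closed of 48 peaks at 8 h (2 and 2 adjusted over the list alone, 2 and 0 after centring; adjusted p = 0.0130 toward opening, but adjusted p = 0.213 with an estimated correlation). Immediate early and AP-1 genes had 4 opened and 2 closed of 112 peaks at 8 h (4 and 2 adjusted over the list alone, 7 and 1 after centring; adjusted p = 0.00256 toward opening, but adjusted p = 0.213 with an estimated correlation). Klf2, a Kruppel-like factor, had a log2 fold change of 0.58 ± 0.13 and Egr1 of -0.56 ± 0.13. The circadian clock list had 6 opened and 5 closed of 50 peaks at 16 h (6 and 5 adjusted over the list alone, 20 and 4 after centring; adjusted p = 0.00101 toward opening, but adjusted p = 0.172 with an estimated correlation). Autophagy and lysosome had 3 opened and 2 closed of 74 peaks at 16 h (3 and 1 adjusted over the list alone, 14 and 0 after centring; adjusted p = 0.00268 toward opening, but adjusted p = 0.267 with an estimated correlation). Gluconeogenesis had 0 opened and 1 closed of 18 peaks at 16 h by limma, with 5 opened at an unadjusted p under 0.05 and 6 by edgeR (0 and 1 adjusted over the list alone, 7 and 1 after centring; adjusted p = 0.0414 toward opening, but adjusted p = 0.267 with an estimated correlation). NF-kB inflammatory response had 1 opened and 8 closed of 124 peaks at 8 h (1 and 8 adjusted over the list alone, 1 and 4 after centring; adjusted p = 0.121). Macrophage lipid handling had 7 opened and 10 closed of 87 peaks at 16 h (6 and 8 adjusted over the list alone, 12 and 4 after centring; adjusted p = 0.123), where centring turns the balance. Acute phase had 2 opened and 3 closed of 9 peaks at 16 h (2 and 4 adjusted over the list alone; adjusted p = 0.803). Bile acid and xenobiotic metabolism had 3 opened and 1 closed of 10 peaks at 16 h (4 and 1 adjusted over the list alone, 4 and 1 after centring; adjusted p = 0.107). Amino acid catabolism and urea cycle had 0 opened and 0 closed of 16 peaks at 3 h by limma, against 1 and 0 at an unadjusted p under 0.05 and 0 and 0 by edgeR (0 and 0 adjusted over the list alone; adjusted p = 0.343). The growth hormone and STAT5 axis had 0 opened and 0 closed of 25 peaks at 3 h by limma, against 0 and 3 at an unadjusted p under 0.05 and 0 and 0 by edgeR (0 and 0 adjusted over the list alone; adjusted p = 0.20). More peaks passed at other times, among them 11 opened and 7 closed of the immediate early list at 16 h. Closed peaks numbered 8 for insulin signalling and 4 for the growth hormone axis at 16 h, and 8 for fatty acid synthesis at 24 h. Of 68 tests of lists in macrophage nuclei, 26 passed with the preset correlation and 5 with the estimated one as well. The median, the mean and the test differed in sign in 20 tests, of which 4 passed: insulin signalling at 8 h, immediate early genes at 8 and 16 h and the clock list at 16 h, each higher than other peaks by the test.

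Marker genes of liver cell types were tested and are given in the same way. In hepatocyte nuclei, hepatocyte markers had 16 opened and 24 closed of 123 peaks at 8 h (16 and 24 adjusted over the list alone, 12 and 33 after centring; adjusted p = 0.0438 toward closing, but adjusted p = 0.732 with an estimated correlation). Kupffer cell and macrophage markers had 4 opened and 0 closed of 14 peaks at 3 h by limma, with 0 closed at an unadjusted p under 0.05 and 0 by edgeR (5 and 0 adjusted over the list alone; adjusted p = 0.0639). Sinusoidal endothelial markers had 2 opened and 5 closed of 16 peaks at 16 h (3 and 5 adjusted over the list alone; adjusted p = 0.333). Cholangiocyte markers had 1 opened and 4 closed of 11 peaks at 16 h (3 and 5 adjusted over the list alone, 1 and 5 after centring; adjusted p = 0.439). Lymphocyte markers had 2 opened and 0 closed of 5 peaks at 16 h by limma, with 0 closed at an unadjusted p under 0.05 and 0 by edgeR (2 and 0 adjusted over the list alone, 0 and 0 after centring; adjusted p = 0.439). Monocyte and neutrophil markers had 0 opened and 0 closed of 7 peaks at 8 h by limma, against 1 and 0 at an unadjusted p under 0.05 and 0 and 0 by edgeR (0 and 0 adjusted over the list alone; adjusted p = 0.587). The stellate and fibroblast list had 1 peak, opened at 3 h (log2 fold change 1.61, list test adjusted p = 0.0917). In macrophage nuclei, Kupffer cell and macrophage markers had 2 opened and 27 closed of 97 peaks at 16 h (2 and 31 adjusted over the list alone, 3 and 19 after centring, list test adjusted p = 0.0758). Of all macrophage peaks at that time, 1144 were opened and 5271 closed as deposited, and 3063 and 3183 after centring. Hepatocyte markers had 0 opened and 2 closed of 3 peaks at 24 h by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR (0 and 2 adjusted over the list alone; adjusted p = 0.00628 toward closing, but adjusted p = 0.0519 with an estimated correlation). Cholangiocyte markers had 0 opened and 2 closed of 2 peaks at 16 h by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR (0 and 2 adjusted over the list alone, 0 and 1 after centring; adjusted p = 0.361). Monocyte and neutrophil markers had 2 opened and 4 closed of 18 peaks at 16 h (2 and 4 adjusted over the list alone, 3 and 2 after centring; adjusted p = 0.412). Sinusoidal endothelial markers had 0 opened and 4 closed of 13 peaks at 16 h by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR (0 and 5 adjusted over the list alone, 0 and 3 after centring; adjusted p = 0.488), and at 24 h 3 closed. Stellate and fibroblast markers had 0 opened and 1 closed of 2 peaks at 16 h by limma, with 0 opened at an unadjusted p under 0.05 and 0 by edgeR (0 and 1 adjusted over the list alone; adjusted p = 0.488). Lymphocyte markers had 0 opened and 0 closed of 9 peaks at 16 h by limma, against 0 and 0 at an unadjusted p under 0.05 and 0 and 0 by edgeR (0 and 0 adjusted over the list alone; adjusted p = 0.412).

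**Figure D1:**
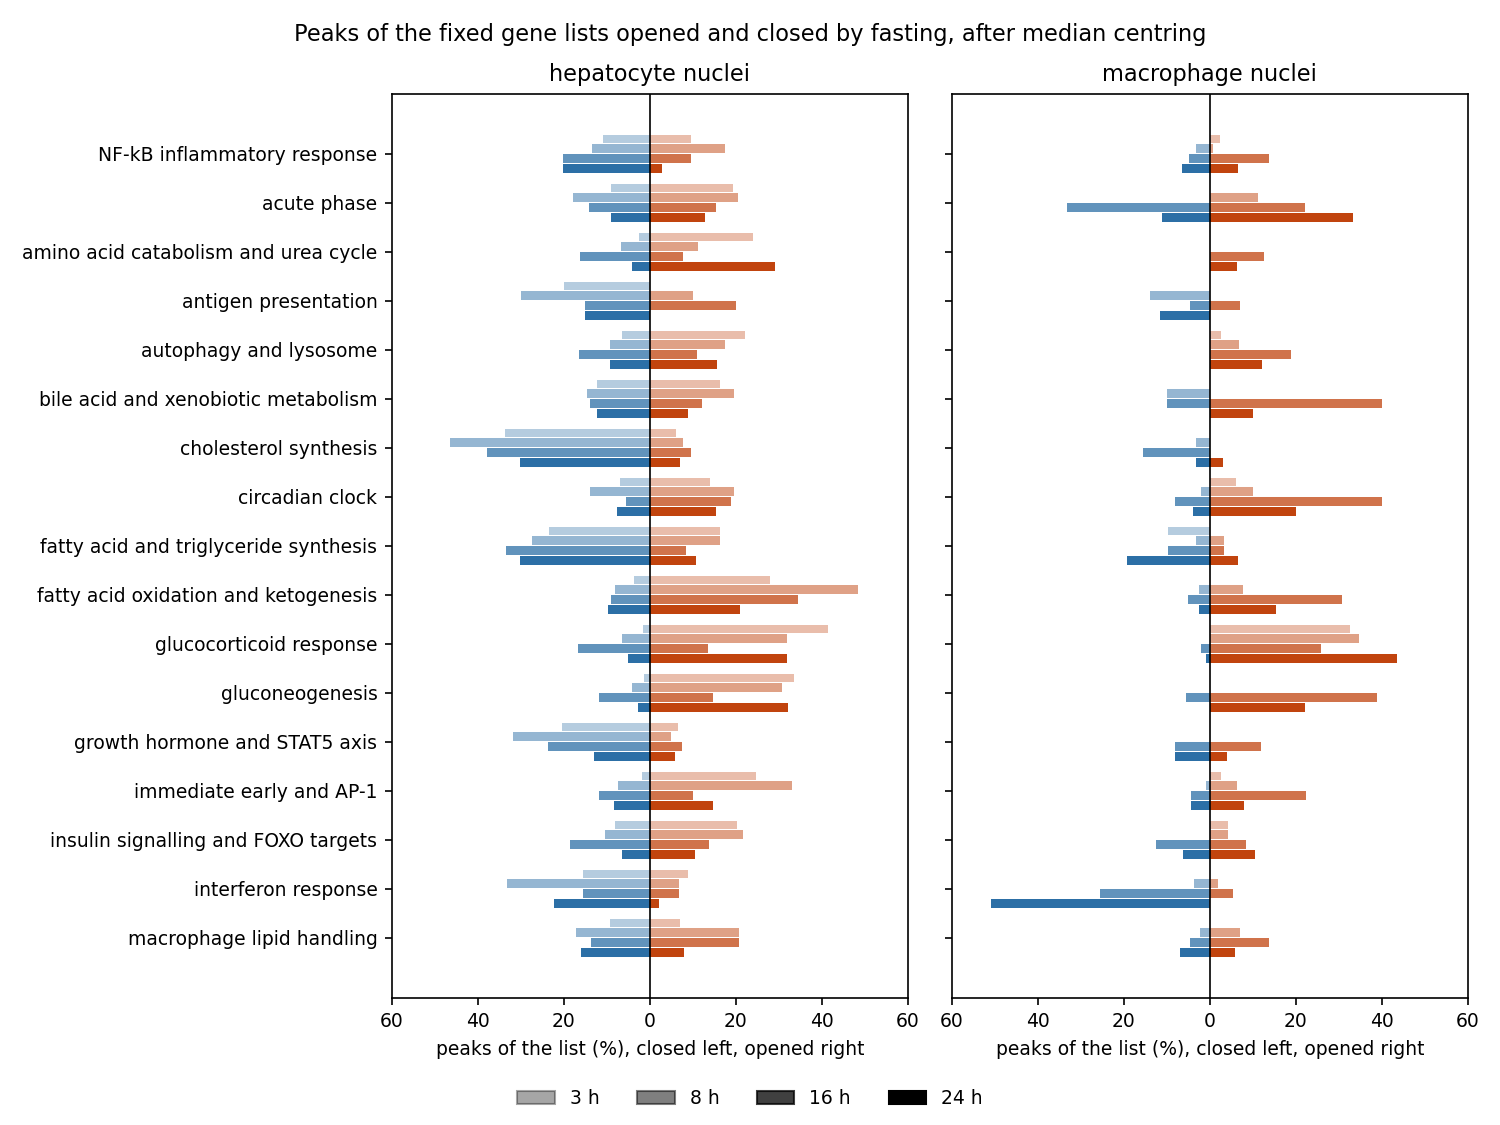
Percent of the peaks of each fixed list closed (left) and opened (right) by fasting at each time after median centring, with darker bars for later times. As deposited, the side with more peaks is the other one in 9 of 68 list tests in hepatocyte nuclei and 8 of 68 in macrophage nuclei.

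The effect of fasting differed between times in 11274 hepatocyte peaks (24.1% of those tested) and 1054 macrophage peaks (3.49%), by limma's test of fasting by time. Among the peaks named by the rule that passed this test, 6 were opened at 1 time and closed at another. Their p values of fasting by time were part of this choice and are no further support. In hepatocyte nuclei a peak near Cyp7a1 (chromosome 4, 6265688 to 6265888) had log2 fold changes of -1.48 ± 0.19 at 3 h and 0.51 ± 0.19 at 16 h (adjusted p of fasting by time = 2.07e-05). A peak near Fgg, the fibrinogen gamma chain, had 0.89 ± 0.26 at 3 h and -1.66 ± 0.26 at 16 h. One near Ccl2 had 0.93 ± 0.15 at 8 h and -0.38 ± 0.15 at 24 h, and one near Ier3, an immediate early gene, had 1.25 ± 0.24 at 16 h and -0.71 ± 0.24 at 24 h. The calls of Cyp7a1 at 16 h and of Ccl2 at 24 h lay near the threshold (limma adjusted p = 0.0417 and 0.0498). In macrophage nuclei a peak near Cd163, a haemoglobin scavenger receptor, had 0.37 ± 0.09 at 3 h and -0.37 ± 0.09 at 16 h (adjusted p of fasting by time = 0.00123). The macrophage count moves with single mice, to 590 without fasted 3 h replicate 4, 644 without fed 3 h replicate 1, 681 without fasted 3 h replicate 3 and 1595 without fasted 16 h replicate 2. It is 286 without the 16 h mice, a setting chosen after seeing the data.

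In fed mice alone, time changed 9893 hepatocyte peaks (21.1%) and 491 macrophage peaks (1.63%), the latter falling to 296 without fed 24 h replicate 4. The macrophage libraries of 3 and 8 h belong to other sets of library numbers than those of 16 and 24 h, so that differences between the earlier and the later pair of times are not separated from set there. The clock peaks named here were chosen after their values were seen, among those of smallest p in the clock list. In hepatocyte nuclei the peak near Npas2, a partner of BMAL1, stood at 43.9 ± 15.6 at 3 h, 112 ± 11.9 at 8 h, 72.2 ± 9.66 at 16 h and 19.6 ± 2.04 at 24 h in fed mice (adjusted p = 8.42e-11 for time). That near Nr1d1 stood at 48.0 ± 4.25 at 3 h, 39.9 ± 4.18 at 8 h, 129 ± 11.3 at 16 h and 86.8 ± 12.2 at 24 h in fed mice. In fasted mice it stood at 92.0 ± 16.5 at 3 h, 111 ± 16.4 at 8 h, 171 ± 14.7 at 16 h and 115 ± 7.22 at 24 h. Its fasting effect differed between times (adjusted p = 0.000102). In macrophage nuclei the same Nr1d1 peak stood at 158 ± 24.6 at 3 h, 89.0 ± 15.6 at 8 h, 168 ± 16.5 at 16 h and 180 ± 8.00 at 24 h in fed mice (adjusted p = 1.16e-09 for time). The promoter peak of Dbp, a transcription factor of clock output, stood at 68.1 ± 7.86 at 3 h, 31.9 ± 5.39 at 8 h, 35.4 ± 12.9 at 16 h and 83.7 ± 11.8 at 24 h (adjusted p = 1.01e-07).

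**Figure D2:**
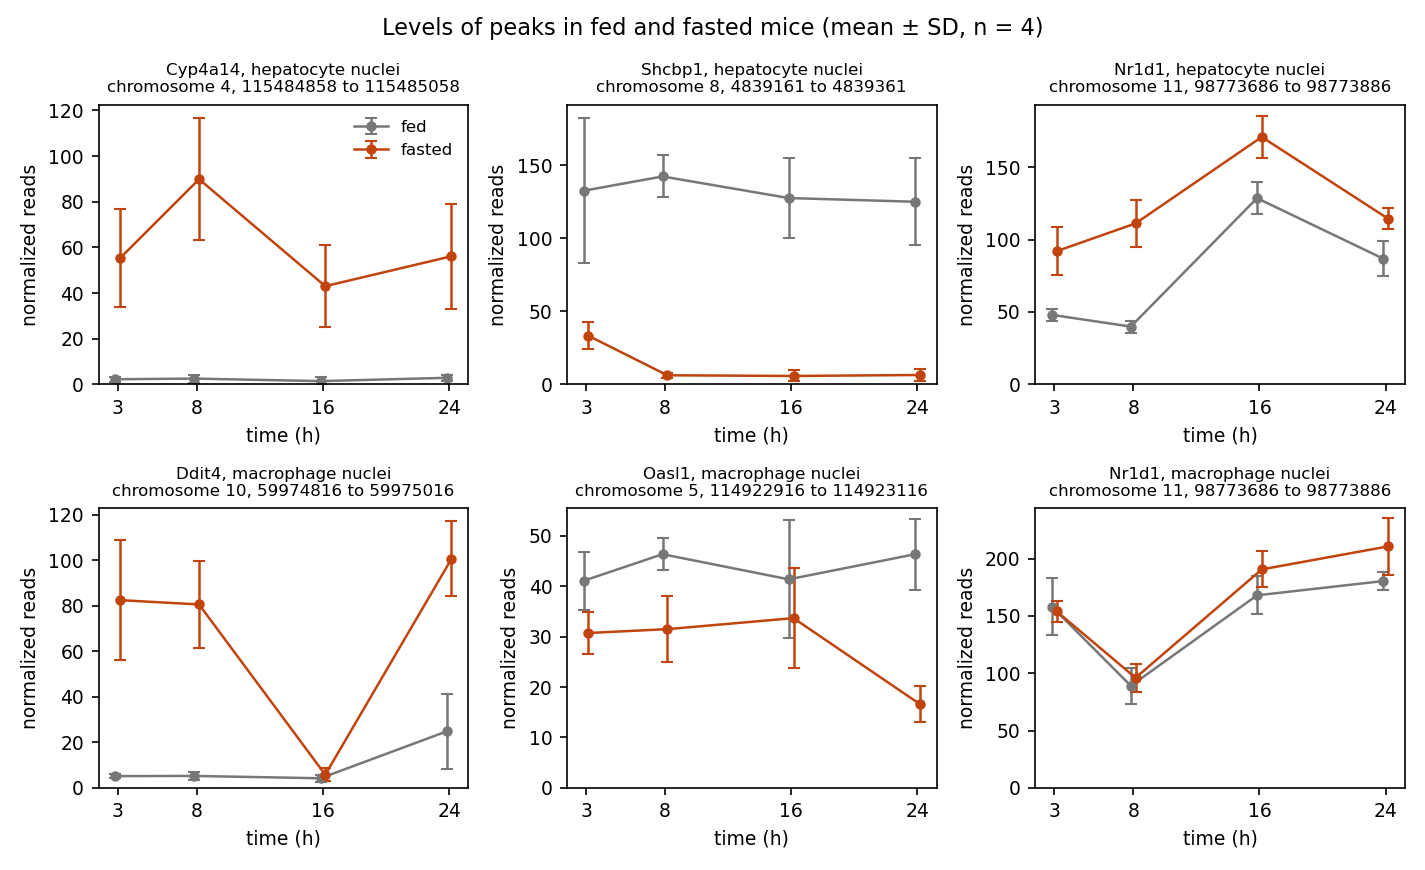
Normalized reads (mean ± SD, n = 4) at 3, 8, 16 and 24 h in fed and fasted mice for peaks named by their nearest gene, with the Nr1d1 panels chosen after their values were seen. The macrophage Ddit4 peak stood at 80.6 in fasted mice at 8 h, 5.78 at 16 h and 101 at 24 h.

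Opened and closed peaks were shared between times beyond chance in both cell types. Of the hepatocyte peaks opened at 3 h, 3398 (64.2%) were also opened at 8 h, 3.16 times the chance number. The share was 29.1% at 16 h (1.53 times) and 35.4% at 24 h (1.40 times). After centring these shares are 55.9% (3.70 times), 22.5% (1.86 times) and 18.9% (1.89 times). Shares and multiples at 16 and 24 h thus change order, in opposite ways. The shares depend on how many peaks were opened at each time. The multiples divide by the number expected from these counts, but the highest multiple possible falls as the larger count rises. Neither therefore ranks the times free of the counts. The peak near Cyp4a14 and others, 789 in all, were opened at each of the 4 times and 1129 were closed at each, against 431 and 1356 after centring. Of the macrophage peaks opened at 3 h, 47.8% were also opened at 8 h (29.3 times chance), 13.2% at 16 h (3.49 times) and 48.8% at 24 h (16.3 times), while 52 were closed at 16 h. After centring the shares are 51.9% (18.3 times), 19.9% (1.96 times) and 54.8% (9.79 times), and 28 were closed at 16 h. Of those closed at 8 h, 48.8% were also closed at 16 h (2.79 times chance), against 41.2% (3.91 times) after centring. The largest hypergeometric p of the 24 overlaps was 0.000381. This test treats peaks as independent, and each time has its own mice and controls.

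Of the macrophage peaks, 14136 (46.9%) overlap a hepatocyte peak by at least 1 bp. Of the 506 macrophage peaks opened at 3 h, 131 lay on a hepatocyte peak and 94 of these were opened there too, against 9.34 by chance. The corresponding counts were 189 against 56.4 at 8 h, 534 against 201 at 16 h and 429 against 233 at 24 h. Peaks closed in both numbered 11, 49, 115 and 100 at 3, 8, 16 and 24 h, against 0.741, 2.99, 18.9 and 7.54 by chance. Of the closed macrophage peaks, 0, 8, 34 and 20 were opened in hepatocyte nuclei. The chance numbers use values as deposited and do not allow for the promoter share of the peaks, so that part of the excess may come from either. A shared peak near Ddit4 (chromosome 10, 59970148 to 59970348) had log2 fold changes of 2.48 ± 0.45 in hepatocyte and 2.45 ± 0.25 in macrophage nuclei at 3 h. One near Tulp1 had 3.67 ± 0.56 and 2.35 ± 0.24. Both were chosen after their values were seen. At 3, 8, 16 and 24 h, 25.9%, 58.6%, 78.1% and 56.7% of opened macrophage peaks lay on a hepatocyte peak and 40.5%, 6.81%, 18.0% and 16.4% of closed ones, with the higher share among the closed at 3 h and among the opened later, differences not tested. The tables were normalized separately, so that no fold change is tested between the cell types.

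Closed peaks lay away from promoters at each time in both cell types, firmly at all times but 3 h in macrophage nuclei. Peaks within 1 kb of a TSS make up 34.9% of tested hepatocyte peaks but 14.1%, 10.8%, 8.24% and 7.24% of those closed at 3, 8, 16 and 24 h. In macrophage nuclei they make up 46.9% of tested peaks and 31.0%, 12.1%, 21.8% and 17.6% of those closed, with Fisher's exact p = 0.0440 at 3 h, the largest of the 8. At that time 42 peaks were closed, and the p exceeds 0.05 when any of 5 mice is left out (fed 3 h replicates 1, 2 and 4 and fasted 3 h replicates 2 and 3, with shares of 22.2, 43.3, 34.8, 40 and 31.6%). Among opened hepatocyte peaks the share was 27.2%, 32.7%, 37.0% and 56.7%, and after median centring 27.9%, 27.7%, 29.1% and 56.0%, so that the share at 16 h changes sides of that among the other peaks. It also does so when fed 16 h replicate 1, 2 or 4 or fasted 16 h replicate 2 or 4 is left out (31.2, 33.2, 32.7, 34.3 and 34.6%), and the share at 8 h when fed 8 h replicate 2 is (35.2%). Among opened macrophage peaks it was 9.49%, 40.6%, 63.4% and 46.3%, and after centring 7.96%, 52.6%, 69.5% and 57.5%, where those at 8 and 24 h change sides. The share at 24 h as deposited did not differ from that among the other peaks (Fisher's exact p = 0.735). It lies below that share without fed 24 h replicate 1 (34.5%, Fisher's exact p = 6.87e-10), fasted replicate 1 (39.0%, Fisher's exact p = 3.34e-05) or fasted replicate 2 (42.3%, Fisher's exact p = 0.0174). Of peaks opened at least 2-fold, 11.1%, 9.96%, 8.50% and 13.0% lay at promoters in hepatocyte nuclei at 3, 8, 16 and 24 h. In macrophage nuclei these shares were 4.12%, 3.80%, 12% and 2.91%. Of peaks closed at least 2-fold, 6.22%, 5.27%, 5.05% and 5.25% lay at promoters in hepatocyte nuclei. In macrophage nuclei 14.3%, 4.76% and 11.8% of them did at 8, 16 and 24 h, with 1 such peak at 3 h. A low promoter share thus marks large changes in both directions.

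**Figure D3:**
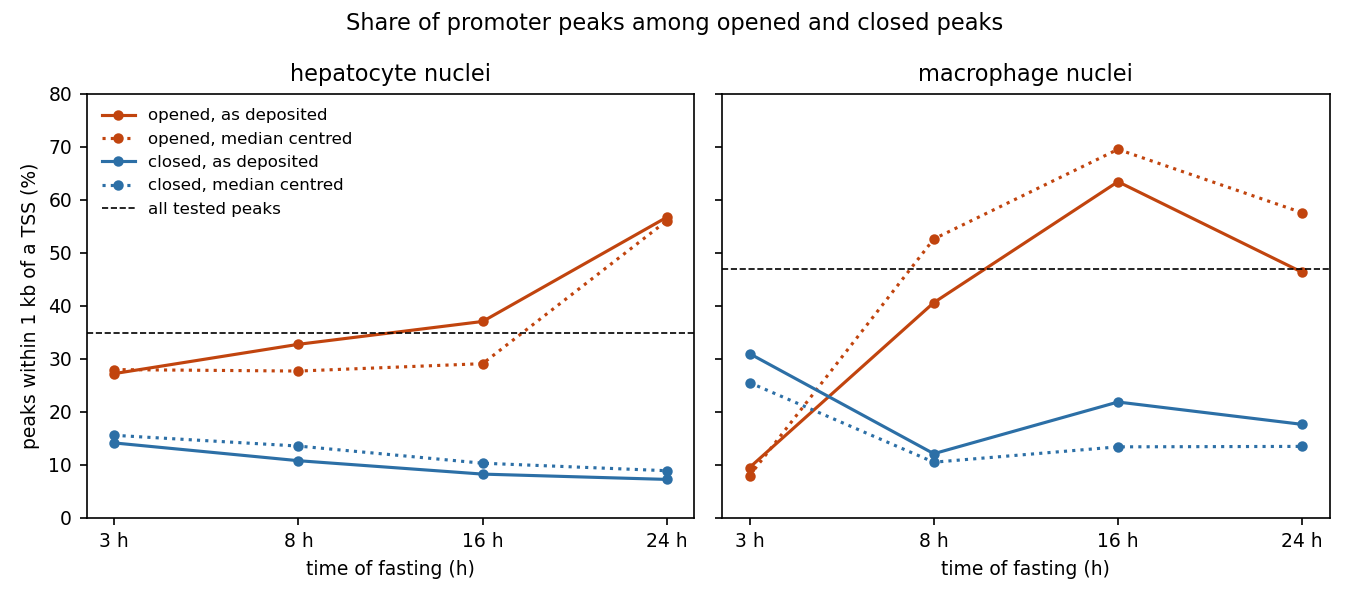
Percent of opened and closed peaks that lie within 1 kb of a TSS at each time, as deposited and after median centring, with the share among all tested peaks as a dashed line. Closed peaks stay below that line at each time under both scalings, and opened macrophage peaks at 8 and 24 h change sides after centring, as do opened hepatocyte peaks at 16 h.

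The authors' own adjusted p values, deposited with the counts, pass the same threshold in 9597, 14357, 12379 and 13369 hepatocyte peaks at 3, 8, 16 and 24 h and in 497, 1694, 4269 and 2997 macrophage peaks. At 3 h, 4767 opened and 4302 closed hepatocyte peaks pass in both tests, and 440 opened and 30 closed macrophage peaks. No peak passed in opposite directions at any of the 4 times. Beside these counts, the 4 fasted mice did not overlap the 4 fed mice in 25.8, 30.9, 22.4 and 36.5% of hepatocyte peaks and 7.41, 14.4, 16.7 and 14.5% of macrophage peaks, where chance gives 2.86%.

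**Figure D4:**
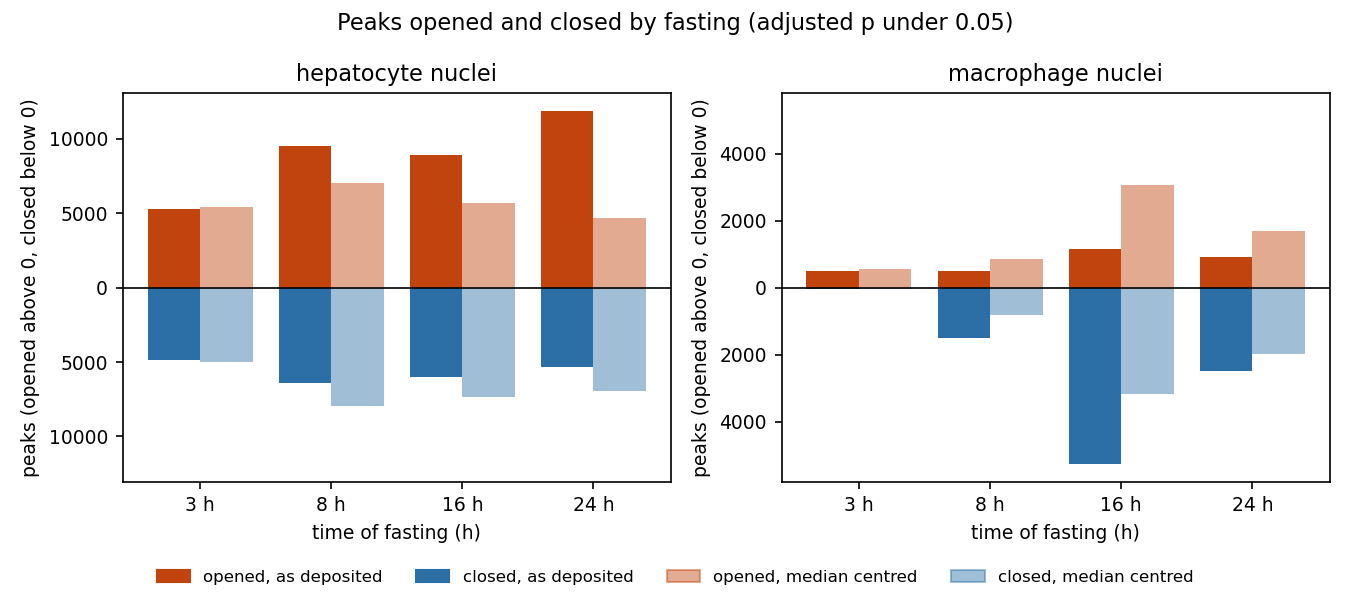
Number of peaks opened (above 0) and closed (below 0) by fasting at each time in hepatocyte and macrophage nuclei (limma, adjusted p under 0.05, n = 4 mice per group), as deposited and after median centring of the libraries. At 24 h the hepatocyte counts are 11867 opened and 5315 closed as deposited, and 4683 and 6936 after centring.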

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

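The comparison within sets of library numbers and that of fed mice at 16 and 24 h were chosen after the result was seen, as were the share without 2 macrophage libraries and the named clock peaks, and the other tests in this part were written down before their results were seen.

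Promoter peaks rose relative to distal peaks in fasted mice, most at 24 h in hepatocyte nuclei, by a log2 difference of 0.22 ± 0.05 (SE), and at 16 h in macrophage nuclei, by 0.20 ± 0.06, with the 4 fasted mice above the 4 fed mice in both. The differences were 0.04 ± 0.02, 0.09 ± 0.04 and 0.14 ± 0.04 at 3, 8 and 16 h in hepatocyte nuclei and -0.02 ± 0.05, 0.18 ± 0.06 and 0.17 ± 0.07 at 3, 8 and 24 h in macrophage nuclei, so that no rise is seen there at 3 h. In macrophage nuclei at 24 h, promoter peaks held 68.2% and 67.0% of reads in fasted replicates 1 and 2. In fed replicates 1 and 2 they held 62.9% and 63.6%. In replicates 3 and 4, of another set of library numbers, they held 67.0% and 66.4% in fasted and 67.2% and 66.2% in fed mice. The rise at that time thus lies in 1 set. At 24 h in hepatocyte and 16 h in macrophage nuclei, promoter and distal peaks matched on height differed by 0.18 ± 0.04 and 0.16 ± 0.05. That keeps 80.6% and 78.2% of the differences. Depth differences would give -0.00134 ± 0.00302 and 0.0129 ± 0.00722. These values argue against height or depth as the whole source. Without fasted 16 h replicates 1 and 4 the promoter share of the 329 opened macrophage peaks at 16 h is 52.3%, against 46.8% among the others (Fisher's exact p = 0.0518). The excess is smaller there and misses the threshold. With any single mouse left out the share is 56.9% to 66.7%. Whether the excess depends on those libraries or fewer mice miss the threshold is thus not told apart. A change in GC bias or in background between libraries was not tested, so that a technical source stays open beside an effect of fasting.

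The 506 macrophage peaks opened at 3 h had median log2 fold changes of 0.79, 0.48, 0.05 and 0.43 at 3, 8, 16 and 24 h (0.79, 0.55, 0.15 and 0.49 after centring), where the choice of peaks at 3 h inflates the value at 3 h but not the later ones. Without fasted 16 h replicates 1 and 4 the median at 16 h was 0.125, against 0.43 at 24 h, and within each of the sets of library numbers that hold both times it was lower at 16 h than at 24 h, by 0.335 in the set with the smaller difference. The fed mice at 16 h lay at a log2 difference of -0.423 from the fed mice at 24 h, and at 0.0296 from those at 3 h, a comparison that the choice of peaks affects and that is not relied on. The values at 16 and 24 h argue against weak libraries, library sets and a rise in the controls, and a candidate explanation is that opening by fasting depends on time of day, with ZT4 at 16 h. Each time was sampled once with its own mice, so that time of day and length of the fast were not separated. The hepatocyte peaks opened at 3 h, from other mice, had median log2 fold changes of 0.70, 0.58, 0.19 and 0.31 at the 4 times. Their median too was lowest at 16 h.

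Hepatocyte nuclei in the macrophage preparation could bring hepatocyte changes into macrophage peaks, although capture of tagged nuclei would remove them. Of 100 hepatocyte marker peaks away from promoters, 1 overlapped a listed macrophage peak, against 8.97% of all such hepatocyte peaks, which argues against a large share of hepatocyte nuclei. The fixed marker list holds 14 genes, of which 2 are also in other lists and 2 have a macrophage peak: Ttr (77.3 ± 12.3 and 61.3 ± 5.35 normalized reads in the 16 fed mice at 2 overlapping peaks) and Apoa2 (34.4 ± 5.62), where the median of all macrophage peaks is 60.5. Of the macrophage peaks opened at 3 h that lie on a hepatocyte peak, 39.7% had the larger log2 fold change in macrophage nuclei. That share lies between the bounds set beforehand, so that for these peaks a macrophage response and carried hepatocyte signal cannot be told apart. At 8, 16 and 24 h the share was 52.2%, 45.7% and 22.6%, with bounds set for 3 h only. The low share at 24 h lies on the side that carried hepatocyte signal would give. Of closed macrophage peaks on a hepatocyte peak, 79.0% fell more in macrophage nuclei at 24 h. A Ttr peak fell in both at 24 h, with log2 fold changes of -0.87 ± 0.13 in macrophage and -1.05 ± 0.22 in hepatocyte nuclei.

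A gap of 1 mouse to the nearest of its group, over the range of the group, passed Dixon's limit in 19 of 306 groups at named peaks, 1 of 80 at clock peaks and 3 of 48 for depth and scaling, where chance gives about 1 in 20. The reads in peaks of macrophage fasted 8 h replicate 4 stood at 3137657, against 3766331 to 3893612 in the others of its group (gap 0.832). The log2 of the median ratio to the other libraries of hepatocyte fed 16 h replicate 3 stood at 0.11, against 0.01 to 0.02 in the others of its group (gap 0.847). The log2 of the median ratio to the other libraries of hepatocyte fasted 16 h replicate 3 stood at 0.18, against 0.11 to 0.12 in the others of its group (gap 0.939). In hepatocyte fasted 3 h mice the peak of Pdk4 stood at 173 normalized reads in replicate 1 against 105 to 114 (gap 0.868). In hepatocyte fed 3 h mice the peak of Lpin1 stood at 6.53 normalized reads in replicate 4 against 12.3 to 13.5 (gap 0.837). In hepatocyte fed 3 h mice the peak of Angptl4 stood at 14.8 normalized reads in replicate 1 against 19.6 to 20.6 (gap 0.831). In hepatocyte fasted 8 h mice the peak of Bnip3 stood at 84.7 normalized reads in replicate 1 against 43.8 to 50.6 (gap 0.834). In hepatocyte fasted 8 h mice the peak of Tap2 stood at 2.76 normalized reads in replicate 4 against 12.1 to 13.5 (gap 0.865). In hepatocyte fasted 16 h mice the peak of Fbp1 stood at 21.6 normalized reads in replicate 1 against 32.1 to 33.2 (gap 0.904). In hepatocyte fed 16 h mice the peak of Cyp4a14 stood at 4.25 normalized reads in replicate 4 against 0 to 0.699 (gap 0.835). In hepatocyte fed 16 h mice the peak of Stk38l stood at 143 normalized reads in replicate 2 against 67.1 to 79.6 (gap 0.836). In hepatocyte fed 16 h mice the peak of Fbp1 stood at 31.4 normalized reads in replicate 3 against 65.9 to 71.3 (gap 0.864). In hepatocyte fed 24 h mice the peak of Got1 stood at 51.4 normalized reads in replicate 1 against 69.1 to 70.7 (gap 0.916). In hepatocyte fed 24 h mice the peak of Ddit4 stood at 24.5 normalized reads in replicate 3 against 35.9 to 37.9 (gap 0.847). In hepatocyte fed 24 h mice the peak of Thrsp stood at 32.4 normalized reads in replicate 4 against 23.9 to 25.2 (gap 0.847). In macrophage fasted 3 h mice the peak of Tsc22d3 stood at 41.3 normalized reads in replicate 2 against 65.4 to 70.1 (gap 0.836). In macrophage fasted 3 h mice the peak of Nfkbia stood at 180 normalized reads in replicate 4 against 153 to 155 (gap 0.924). In macrophage fed 8 h mice the peak of Egr1 stood at 80.1 normalized reads in replicate 4 against 99.9 to 102 (gap 0.884). In macrophage fasted 16 h mice the peak of Usp18 stood at 96.7 normalized reads in replicate 1 against 119 to 123 (gap 0.852). In macrophage fed 16 h mice the peak of Thsd4 stood at 51.3 normalized reads in replicate 4 against 39.6 to 41.5 (gap 0.839). In macrophage fed 16 h mice the peak of Tfeb stood at 20.1 normalized reads in replicate 1 against 25.7 to 26.4 (gap 0.885). In macrophage fed 24 h mice the peak of Srebf1 stood at 139 normalized reads in replicate 3 against 106 to 111 (gap 0.847). In macrophage fed 24 h mice the clock peak of Tef stood at 152 normalized reads in replicate 4 against 108 to 110 (gap 0.960).

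The fasting effect differed between times in 11274 hepatocyte and 1054 macrophage peaks. Named peaks opened at 1 time and closed at another were chosen also for passing the test of fasting by time. Its adjusted p was 2.07e-05 for Cyp7a1, 5.18e-05 for Fgg, 0.000463 for Ccl2 and 0.000824 for Ier3 in hepatocyte nuclei. In macrophage nuclei it was 0.00123 for Cd163.

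For each comparison of fasted and fed mice, the real split was the 1 of 35 splits of its 8 mice that called as many peaks. A first rank among 35 is the most that 4 against 4 mice can give, so that chance is made less likely but not excluded. In hepatocyte nuclei the real split called 10136 peaks at 3 h against at most 78 in another split and 15937 peaks at 8 h against at most 928 in another split. Hepatocyte nuclei also gave 14896 peaks at 16 h against at most 5241 in another split and 17182 peaks at 24 h against at most 1 in another split. In macrophage nuclei it called 548 peaks at 3 h against at most 34 in another split and 1990 peaks at 8 h against at most 2 in another split. Macrophage nuclei also gave 6415 peaks at 16 h against at most 1766 in another split and 3402 peaks at 24 h against at most 115 in another split. The highest other split at 16 h exchanges fasted replicate 4 with fed replicate 3 in hepatocyte nuclei and fasted replicate 2 with fed replicate 4 in macrophage nuclei. With times redrawn in 100 assignments, the real one included, only the real one called as many peaks for fasting by time (11274 in hepatocyte nuclei, at most 2824 otherwise, and 1054 in macrophage nuclei, at most 103 otherwise). The same held for time in fed mice (9893 and at most 781 in hepatocyte nuclei, 491 and at most 173 in macrophage nuclei). With 100 assignments this makes chance unlikely for time in fed mice but does not exclude it. For fasting by time, redrawing the times also breaks the effect of time that fed and fasted mice share, which adds spread. The redrawn counts can therefore not decide whether chance gave the counts for fasting by time. The macrophage libraries of 3 and 8 h and those of 16 and 24 h belong to different sets of library numbers, so that a difference between sets stays open for changes from the earlier to the later pair of times.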

How the results depend on the processing

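Reads as a covariate, the leaving out of fasted 16 h macrophage replicates 1 and 4 and the leaving out of the 16 h mice were chosen after seeing the data. The other alternatives were fixed before the data were examined. Of 280 recomputed counts, 245 stayed within 1.5 times the main count. Of 8540 values of named peaks, 8140 kept their direction and call, and the other 400 kept their direction but missed the threshold, 49 hepatocyte and 118 macrophage peaks of them under the minimum fold. Of 816 list tests, 739 kept direction and side, 57 lost and 19 gained the call and 1 reversed. Of the lost calls, 23 in hepatocyte and 21 in macrophage nuclei went with the estimated correlation. Of 276 values for peaks shared between times, 274 stayed on their side of chance. The causes of the changes below were not tested except where stated.

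Quantile normalization gave 10990 peaks in hepatocyte nuclei at 24 h, and in macrophage nuclei 4035 at 16 h, 699 for fasting by time and 747 for time in fed mice. A fit of only the 2 groups compared, which estimates the spread from 8 mice, gave 9091 hepatocyte peaks at 16 h and 877, 3380 and 3391 macrophage peaks at 3, 8 and 16 h. A minimum fold of 2, which by construction lowers counts, gave 2346, 3971, 3166 and 2225 hepatocyte and 171, 100, 172 and 239 macrophage peaks. DESeq2 gave 4229 macrophage peaks at 16 h. Without fasted 16 h replicates 1 and 4 there were 1476 at 16 h and 639 for fasting by time, and without the 16 h mice 286 for fasting by time.

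With each mouse left out in turn, hepatocyte counts ranged over 7403 to 10077 at 3 h, 13053 to 15597 at 8 h, 11684 to 15565 at 16 h and 12805 to 16651 at 24 h, over 9116 to 13335 for fasting by time and 7738 to 9497 for time in fed mice. Macrophage counts ranged over 319 to 540, 695 to 2700, 3822 to 7169 and 1824 to 3908, over 590 to 1595 for fasting by time and 296 to 502 for time in fed mice.

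The promoter share of opened hepatocyte peaks at 16 h was above that of the other peaks as deposited and below it with median centring (29.1%), quantile normalization (23.0%), limma without a trend (34.6%), the minimum fold (8.50%), edgeR (28.0%), DESeq2 (27.6%) and any of 5 mice left out (31.2% to 34.6%), with a range of 31.2% to 41.8% over the 8 mice. That at 8 h ranged over 27.9% to 35.2% with mice left out and crossed without fed 8 h replicate 2. That at 24 h fell below the others with the minimum fold (13.0%). Among opened macrophage peaks the share crossed to above that of the others at 8 h with centring (52.6%), edgeR (58.1%) and DESeq2 (51.3%), and at 24 h with centring (57.5%), edgeR (58.2%), DESeq2 (55.3%) and reads as a covariate (56.0%). At 16 h it was 12% with the minimum fold and 52.3% without the 2 libraries, where the difference misses the threshold.

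The difference at 8 h in macrophage nuclei also missed the threshold with quantile normalization (44.9%), the block on library sets (43.6%) and without fasted 8 h replicate 1, with a range of 26.4% to 44.0% over the mice. The one at 24 h passed it, below the others, with quantile normalization (38.8%), only the 2 groups (41.8%), limma without a trend (40.4%), the minimum fold (2.91%), and without fed 24 h replicate 1 or fasted 24 h replicate 1 or 2, with a range of 34.5% to 48.6% over the mice. The lower share of promoters among closed macrophage peaks at 3 h missed it with an offset of 0.5 (31.7%), a minimum mean of 30 (34.5%), limma without a trend (34.2%), the minimum fold (0%), reads as a covariate (37.0%) and any of 5 mice left out (22.2% to 43.3%), with a range of 13.6% to 43.3% over the 8 mice.

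Macrophage lipid handling in hepatocyte nuclei at 24 h had an adjusted p of 0.719 and, with promoter peaks only, 0.0184 in the other direction. Its adjusted p ranged over 0.0184 to 0.871 among its alternatives. The overlap of closed macrophage peaks at 3 h with those at 8 and at 16 h was 0 and 0 times chance with the minimum fold, where 1 closed peak is left at 3 h. Single technical runs of macrophage libraries were not run, since 1 column per mouse is deposited, and the motif test was not run for want of a genome sequence. Leaving out the low-value filter changed no tested peak in macrophage nuclei and says nothing there. The block on library sets was not run for time in macrophage nuclei, where a set holds 2 of the 4 times. Small changes can be missed at this depth. Changes of 1.5-fold were found in 34% of simulated cases in hepatocyte nuclei at 16 h, where 200 peaks were changed. More peaks passed in the data, so that this share is not an estimate for them.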

Other observations

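Some macrophage peaks that fasting opened also rose late in fed mice, and those given here were singled out after their values were seen. The Ddit4 peak described for 3 h had means of 5.16, 5.23, 4.21 and 24.8 normalized reads in fed mice at 3, 8, 16 and 24 h, with an SD of 16.4 at 24 h (n = 4, adjusted p = 7.50e-06 for time). A peak near Mrap, an accessory protein of the ACTH receptor (chromosome 16, 90743579 to 90743779), had fed means of 11.6, 10.5, 12.2 and 43.5 (adjusted p = 1.38e-08). Its log2 fold changes with fasting were 2.17 ± 0.21, 2.28 ± 0.21, 0.53 ± 0.21 and 0.88 ± 0.21 (SE). A peak near Armc12 (chromosome 17, 28513925 to 28514125) had fed means of 16.6, 11.6, 14.2 and 45.8, with an SD of 20.3 at 24 h (adjusted p = 2.41e-06), and log2 fold changes of 2.38 ± 0.23, 2.61 ± 0.23, 0.35 ± 0.23 and 1.49 ± 0.23. The fasting effect differed between times at Ddit4 (adjusted p = 2.26e-07), Mrap (7.03e-05) and Armc12 (1.66e-05).

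Clock peaks were chosen after their values were seen. That near Per3, a clock repressor, stood at 53.2 ± 10.4 at 3 h, 31.2 ± 3.22 at 8 h, 21.3 ± 3.40 at 16 h and 62.9 ± 2.23 at 24 h in fed hepatocyte nuclei (mean ± SD). In fasted ones it stood at 51.1 ± 8.49 at 3 h, 49.1 ± 6.80 at 8 h, 35.8 ± 9.90 at 16 h and 57.0 ± 3.46 at 24 h (adjusted p = 0.0117 for fasting by time). In fed macrophage nuclei the promoter peak of Tef, a clock output factor, stood at 134 ± 13.4 at 3 h, 105 ± 15.5 at 8 h, 82.0 ± 13.4 at 16 h and 120 ± 21.6 at 24 h (adjusted p = 0.000304 for time).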
